A study of Mus musculus with 8 samples.

How the data were processed

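RNA was measured on 8 one-colour Agilent whole mouse genome arrays (design 014868) from donor-derived haematopoietic stem cells (HSC), sorted by flow cytometry out of mice that had received wild-type (WT) or E47 knockout (KO) cells. Per the labels' protocols, the sorted cells were lysed, their mRNA was turned into cDNA and amplified by a PCR that copies all transcripts (the SuperAmp service of a company), and the amplified cDNA was labelled with Cy3. Amplification of this kind serves samples of few cells, and unequal copying of cDNA molecules can add to the spread between arrays. Genotype and recipient (primary or secondary) were taken from the sample titles, which give 4 groups of 2 arrays. The series' design text speaks of replicates from 4 samples, which leaves open whether the 2 arrays of a group hold separate cell samples, so p-values measure only the spread between these arrays, which may be technical.

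The deposited scanner files hold spot intensities on a linear scale, made with Agilent Feature Extraction 10.5.1.1 per the file headers: a processed signal, already background-subtracted, a mean signal, a local background and quality marks for each spot. The deposited series matrix holds a ratio to the array's own median: each of its columns had a median of 1 and, multiplied by the median processed intensity of its array, lay between 0.999946 and 1.000052 times the scanner value. Its scale and centring were therefore known from this comparison, and it was used only as an alternative. Scan settings other than those in the headers are not given in the sources used here.

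Each array had 43379 spots that were not controls, for 41174 probes, of which 245 were spotted 10 times. Spots marked as outliers were left out, spots of one probe were averaged, and 41048 probes kept a value on every array; no spot was saturated. The main value was log2 of the processed intensity minus the array's own 75th percentile of it. Probes were named through their accession with the mouse gene table of assembly GRCm38.p6, used for names only (24375 probes by their first accession, 115 by another and 4655 through a probe of the same name); 9910 kept the name in the file and 2119 had none. Probe positions are those of the files, in mm8. A gene was represented by the probe with the highest mean over the 8 arrays. A gene was tested if one of its probes was well above background on both arrays of at least 1 group, which left 22994 genes and unnamed probes, 16477 of them with a symbol.

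Groups were compared with limma 3.58.1 in R 4.3.3 (lmFit and eBayes) in one fit over the 4 groups, with 4 residual degrees of freedom, and with an additive model of genotype and recipient (5 residual degrees of freedom) for the comparisons over all 8 arrays. P-values were adjusted by the Benjamini-Hochberg method and the threshold was an adjusted p under 0.05. The genotype comparisons, their interaction, and secondary against primary recipients within each genotype were fixed before the data were examined; secondary against primary recipients over both genotypes was added afterwards. The median gene shifted by up to -1.03 on the log2 scale between groups, so log2 changes are given relative to the median of all genes tested. P-values, and the counts of genes higher or lower, refer to the change before this centring. Where a probe was not well above background on any array of the dimmer group, "at least N-fold" sets the brighter group's mean against the mean, over the dimmer group's arrays, of the lowest signal among probes well above background or the probe's own signal if that was higher.

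Gene lists, 24 of them with 673 of 679 entries matched, were fixed before the data were examined. They cover HSC identity, lineage markers of the other blood cells a sort could hold, cell cycle, metabolism and stress, and each is named with its result in the text. A list was tested for standing apart from all other genes with limma's camera at a preset correlation between genes of 0.01, two-sided, with adjustment over the lists of one comparison, and again with the correlation estimated from the arrays; fry, which tests whether the list's own genes move on balance one way, was run beside it. Members were also counted with p-values adjusted over the list alone. After the data were seen, the median of a list was also set beside the medians of 10000 random lists matched on mean level. Also afterwards, the median log2 level of a list per array, relative to all genes of that array, was compared between 4 and 4 arrays. That comparison used an exact two-sided permutation test over 70 arrangements.

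Genes named in the text follow a rule fixed beforehand: the 12 largest changes per direction past the threshold (5 outside the genotype comparisons), or, where fewer than 5 genes passed in a direction, as was the case in every comparison, the 10 or 5 of lowest p. Clone and accession style names were left out. Such genes had to be well above background on every array of the brighter group with no overlap between groups, except in the interaction, for which the rule as fixed named no brighter group and 2 arrays well above background sufficed. The rule adds, in each list, the 4 largest changes past the test or the 2 members of lowest p where none passed, Tcf3, and a fixed set of cell cycle, lineage and sex-linked genes. The comparison added later follows the rule with 10 per direction.

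Arrays lay on 3 slides. Slide 1 held all WT arrays, and each KO group had a slide of its own, so slide and genotype cannot be told apart, while secondary against primary WT recipients is a comparison within slide 1. Replicate numbers occur only as 1 and 2 in each group. The alternatives tried were normexp background correction of the mean signal (offset 50), quantile normalization, scaling by genes well above background on all 8 arrays, the series matrix, no filter, a stricter filter, every probe by itself, the mean over the probes of a gene, another variance model, a minimum change of 2-fold, only the arrays compared, the replicate number as a block, slide as a random block, averaging the arrays of a group first and leaving out each array. Chosen after the data were seen were scaling by the 75th percentile of probes well above background on all arrays, leaving out the 2 arrays with the fewest spots above background, and limma's array weights.

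The fits were tested on simulated data with the measured spread of the 22994 genes and 50 changed genes per size. A gene had the same pooled spread on every array, and genes were drawn independently of each other. The larger spread of arrays with low signal was not simulated. Comparisons of KO with WT within a kind of recipient, and of recipients within a genotype, were thus simulated alike. Differences in recovery between them come from the random draw. For a log2 change of 8, the comparison of KO with WT recovered 22% of the changed genes in primary and 46% in secondary recipients, and the interaction recovered 0%. Secondary against primary recipients recovered 12% in WT and 26% in KO cells at that size. At a change of 4 these 5 comparisons recovered 0%. The comparisons over all 8 arrays recovered 16% (KO against WT) and 14% (secondary against primary) of the genes changed by 4, and 78% and 72% of those changed by 6. A list of genes shifted by -2 was recovered in every comparison, with 0 other lists. Because the simulated genes were independent, this does not show how often camera calls a list falsely where genes move together. Genes called falsely numbered 7 and 5 in the comparisons over all 8 arrays (KO against WT, secondary against primary), 1 in KO against WT in secondary recipients and 0 in each of the other comparisons. The number of arrays limits the precision of every value.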

Results

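Haematopoietic stem cells (HSC) renew themselves and give rise to all blood cells, and transplanting them from a first set of irradiated mice into a second tests how long they keep doing so. E47 is a splice product of the gene Tcf3, also known as E2A, and a basic helix-loop-helix transcription factor needed for B lymphocyte development. Per its title, the series compared HSC without E47 (KO) with wild-type (WT) HSC, taken as donor-derived cells from primary and from secondary recipient mice. Each of the 4 groups had 2 arrays, and 22994 genes and unnamed probes were tested. The 4 WT arrays lay on 1 slide and each KO group on a slide of its own, so genotype and slide cannot be told apart. Printed log2 changes are relative to the median gene, while limma's p-values test the change before this centring. The labels leave open whether the 2 arrays of a group are separate cell samples, and if they are not, the p-values measure technical spread alone.

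The share of spots well above background was 74.0% and 41.9% on the 2 arrays of WT cells from primary recipients, 72.2% and 35.4% for KO cells from primary recipients, 80.2% and 78.0% for WT cells from secondary recipients, and 90.7% and 74.5% for KO cells from secondary recipients. On the 2 arrays under 50% (replicate 2 of both primary groups, the dim arrays below), the 75th percentile of the signal was 36.6 and 19.6, against 320.7 to 846.9 on the others. Over the 11682 probes well above background on all arrays, replicate 1 of WT and replicate 1 of KO from primary recipients correlated with each other at r = 0.78, and with their own replicates at 0.532 and 0.542. Replicates from secondary recipients correlated at 0.825 (WT) and 0.773 (KO). Replicate 1 of KO from secondary recipients correlated more closely with the WT arrays from secondary recipients, at 0.842 (replicate 1) and 0.846 (replicate 2). Arrays from secondary recipients thus did not group by genotype either. The log2 difference between replicates had a median absolute deviation of 2.02 (WT primary), 2.06 (KO primary), 1.27 (WT secondary) and 1.62 (KO secondary), where the spread of repeated spots within an array predicts an SD of 0.107, 0.138, 0.0870 and 0.105.

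**Figure D1:**
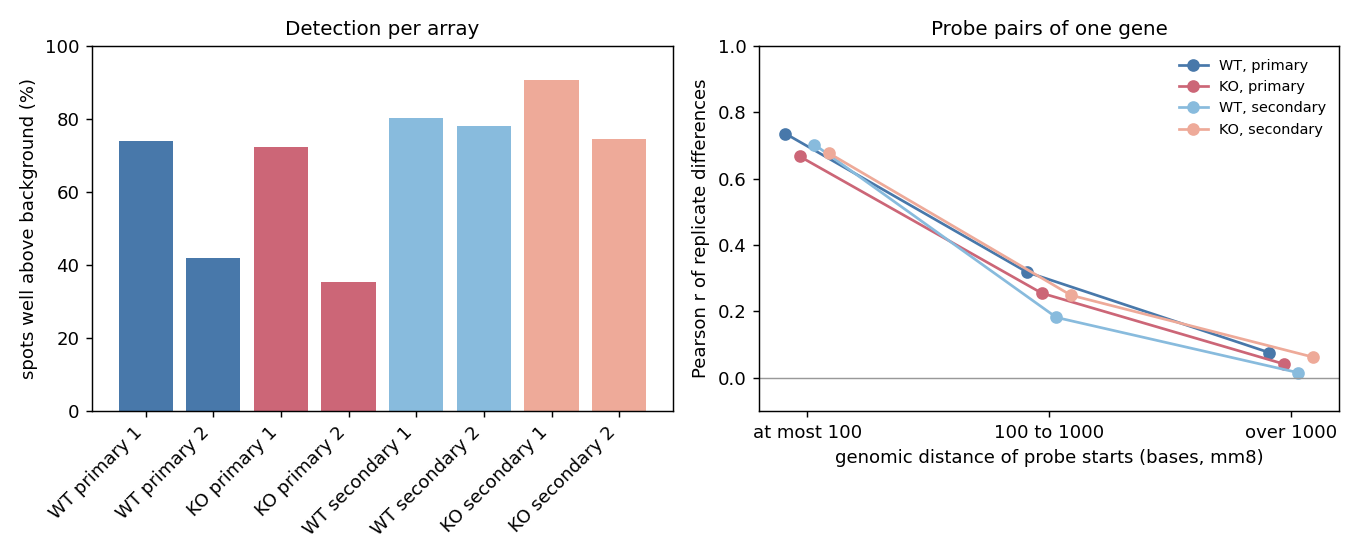
Left, the percentage of spots well above background on each of the 8 arrays. Right, correlation of the log2 difference between the 2 arrays of a group across pairs of probes of one gene, by the distance between probe starts in mm8: 0.667 to 0.736 up to 100 bases apart and 0.0154 to 0.076 over 1 kb apart.

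Tcf3, the gene that encodes E47, was well above background on all 8 arrays. Its brighter probe lies on chromosome 10 at 79816347 to 79816406 (mm8), and its signal was 104 and 1278 in WT and 84 and 101 in KO cells from primary recipients, and 1778 and 1773 in WT and 1664 and 167 in KO cells from secondary recipients. Relative to the median gene, the log2 change of KO against WT was -1.90 (SE 2.39) in primary and -1.65 (SE 2.39) in secondary recipients, with limma adjusted p = 0.997 and 0.983. The other probe, at 79813023 to 79813082, gave 4.84 and 1.24. Whether either probe lies in the deleted part is not given in the sources used here, and Tcf3 also encodes E12, so these values check nothing about the labels.

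KO and WT cells were compared in primary recipients to ask which transcripts differ without E47 after a first transplantation. Genes of oxidative phosphorylation, which make the respiratory chain and ATP synthase, lay lower in KO than other genes: 43 of 61 members lay below the median gene and 18 above, with a median log2 change of -1.23 (camera adjusted p = 0.0093). With an estimated correlation between genes the adjusted p = 0.26, and the fry adjusted p = 0.94. No member passed the test over all genes, 11 had an unadjusted p under 0.05, and 0 passed when adjusted over the list alone. Cox7a2, a subunit of cytochrome c oxidase, had a log2 change of -4.91 (SE 1.44, limma adjusted p = 0.997), while Uqcrh, a subunit of complex III, stood at 5.65 (SE 1.63, limma adjusted p = 0.997). The list's call was lost without replicate 1 of WT primary (adjusted p = 0.39, median -0.28) and without replicate 2 of KO primary (0.96, median -0.62). It was also lost without both dim arrays (0.36), with normexp (0.12) and with quantile normalization (0.096).

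The other 23 lists had camera adjusted p between 0.45 and 0.98 in primary recipients. Among genes that bear on E47 as a lymphoid regulator, the median log2 change was 0.10 for lymphoid priming (adjusted p = 0.98), -0.09 for B lineage genes and known E2A targets (0.98), -0.91 for E proteins, Id proteins and their partners (0.68) and 0.32 for the Notch pathway (0.98). Tcf7, a transcription factor of early T cells, stood at -3.50 (SE 0.98), Rag1, a recombinase of antigen receptor genes, at 3.12 (SE 1.66) and Il7r, the receptor chain for interleukin 7, at 1.87 (SE 1.61). Of cell cycle genes, Ccnd2 (cyclin D2) stood at -7.30 (SE 2.43), Birc5 (survivin, active in mitosis) at 4.69 (SE 1.99) and Cdkn1a (the inhibitor p21) at -1.46 (SE 1.04). The lists of S phase and mitosis (median 0.09, adjusted p = 0.98), G1 cyclins (0.02, 0.88) and CDK inhibitors (0.20, 0.98) did not pass. Of HSC genes, Fgd5, a marker of the most immature cells, stood at 5.37 (SE 1.42), Angpt1, a ligand of the receptor Tek, at 4.23 (SE 1.17) and Kit, the receptor for stem cell factor, at -4.17 (SE 2.71), with a median of -0.39 over the HSC list (0.88). Txnip, which binds thioredoxin, stood at -7.26 (SE 2.39) and Idh2, a mitochondrial isocitrate dehydrogenase, at -9.88 (SE 2.84). Some of these changes rest largely on a lone array. Ccnd2 had scaled log2 levels of 2.30 and 10.46 in WT and of 0.87 and -2.19 in KO cells. Kit had a signal of 253 and 11678 in WT and of 528 and 15 in KO cells, so replicate 1 went the other way. Rag1 had a signal of 30 and 4 in WT and of 2323 and 3 in KO cells.

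In the limma test 0 of 22994 genes passed in primary recipients (lowest adjusted p = 0.997). Of these, 902 had an unadjusted p under 0.05 where 1150 are expected by chance: 446 higher and 456 lower in KO. Those of lowest p higher in KO were Sub1, a transcriptional coactivator (5.99, SE 1.12), Map1lc3b, an autophagosome protein (7.49, SE 1.44), and Mycbp2, a ubiquitin ligase (11.45, SE 2.18). They were followed by Odc1 of polyamine synthesis (6.33, SE 1.31), the protease Furin (7.70, SE 1.58), the cohesin subunit Rad21 (4.84, SE 1.01), St13, Dph5, Smu1 and Ankrd49, the last at least 13.7-fold higher. Those lower in KO were Vav1, a signalling protein of blood cells (-8.16, SE 1.14, chromosome 17, 56997200 to 57000602), Ubap2l (-6.79, SE 0.95) and Hsdl2 (-6.64, SE 0.99). Next came Rp9, Bcdin3d, the mitochondrial ribosomal gene Mrpl24 (-8.52, SE 1.49), Ppm1b, Mthfd1l of mitochondrial folate metabolism (at least 67.8-fold), Drg1 (at least 222-fold) and the DNA repair gene Ddb2 (at least 369-fold). Other probes of several of these genes differed, with 0.96 for Sub1, -0.24 for Map1lc3b, -0.87 for Odc1, 0.20 for Furin, -1.35 for Rad21 and -1.16 for Vav1. Genes passed without replicate 1 of WT primary, nearly all of them lower in KO, but that fit leaves dim replicate 2 as the lone WT array. Ribosomal protein genes stand high on replicate 2: relative to all genes of the array, their median log2 level was 11.753 there and 5.605 on replicate 1.

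In secondary recipients the same comparison asks what differs after a second transplantation. Ribosomal protein genes lay below the median gene for 60 of 60 members, with a median log2 change of -0.64, which did not pass (camera adjusted p = 0.075). Oxidative phosphorylation had a median of -0.84 (46 of 61 below, adjusted p = 0.059), antioxidant genes -0.97 (28 of 36 below, 0.073) and interferon response genes -0.94 (22 of 31 below, 0.075). HSC identity genes had a median of -0.63 (0.14), among them Slamf1, a surface marker of HSC, at -3.88 (SE 1.81). Lymphoid priming stood at 0.28 (0.45), B lineage genes at 0.10 (0.52), E and Id proteins at -0.77 (0.25), the Notch pathway at -0.90 (0.69), S phase and mitosis at 0.20 (0.68), G1 cyclins at -0.95 (0.14) and CDK inhibitors at -0.15 (0.90). Mcm3, a subunit of the replicative helicase, stood at 3.42 (SE 1.14), Brca1 of homologous recombination at -3.24 (SE 0.95), the AP-1 subunit Fos at least 18.3-fold higher in KO, and Cdkn1a at -0.14 (SE 1.04). The fold of Fos holds for the mean of the KO arrays, whose scaled log2 levels were -4.21 and 1.09. None of the 24 lists passed camera. The fry adjusted p was lowest for mast cell markers (0.0053, median 0.32) and lay under the threshold. That test refers to the change before centring, which includes a shift of the median gene by 0.47.

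The limma test passed 0 genes in secondary recipients (lowest adjusted p = 0.744), and 1234 had an unadjusted p under 0.05, 855 higher and 379 lower in KO. Among genes higher in KO, the lowest p belonged to the Wnt co-receptor Lrp6 (7.12, at least 42.9-fold, chromosome 6, 134416031 to 134416090) and the mitochondrial carrier Slc25a16 (8.46, SE 1.32, at least 80.7-fold). Next were Arhgef39 (7.89, SE 1.26), Mamdc2 (5.32, SE 0.96), Ehhadh of peroxisomal fatty acid oxidation (6.17, SE 1.11), Sptssb (at least 44.4-fold), Fbxo24 (at least 47.3-fold), Zfp277, Upf3a and the activin receptor Acvr2a (6.62, SE 1.33). Lower in KO were Ap3m2 of the AP-3 adaptor (-5.27, SE 0.99), Ankrd16 (-5.63, SE 1.06), Rell2, Olfr33, Adat2, the interferon-induced GTPase Gbp4 (-7.12, SE 1.44), Gdf3, Rad52 (-5.52, SE 1.13), Mtcp1 and Mr1.

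Over both kinds of recipient, oxidative phosphorylation genes lay lower in KO (median log2 change -0.90, 46 of 61 below the median gene, camera adjusted p = 0.00012; adjusted p = 0.084 with an estimated correlation). In that list Sdhc of complex II stood at -2.72 (SE 0.78) and Uqcrh at 3.22 (SE 1.35), and 0 members passed when adjusted over the list alone. Ribosomal proteins were also called lower (median -0.49, 45 of 60 below, adjusted p = 0.017, and adjusted p = 0.77 with an estimated correlation). So were antioxidant genes (-0.40, 28 of 36 below, 0.038, and adjusted p = 0.44 with an estimated correlation). The interferon response was called lower too (-0.95, 23 of 31 below, 0.038, and adjusted p = 0.32 with an estimated correlation), and 0 members of these 3 lists passed when adjusted over the list alone. The ribosomal median turned to 0.44 without replicate 2 of WT primary (adjusted p = 0.77) and without replicate 1 of KO primary (0.52), and that call was also lost without replicate 1 of WT secondary (0.07) or of KO secondary (0.066). The antioxidant call was lost without WT primary replicate 2 (0.063), WT secondary replicate 1 (0.07) or 2 (0.13), or KO secondary replicate 1 (0.066) or 2 (0.12). The interferon call was lost without the same arrays (0.063, 0.17, 0.077, 0.066 and 0.12) and without KO primary replicate 2 (0.16). Exact two-sided permutation of the list levels over the arrays, KO against WT, gave p = 0.457 for oxidative phosphorylation, 0.629 for ribosomal proteins, 0.171 for antioxidant genes and 0.2 for the interferon response (adjusted p = 0.814, 0.83, 0.771 and 0.771).

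Single genes of lowest p in this comparison over both recipients were Foxj3 (3.71, SE 0.79), Mettl6 (3.36, SE 0.83), Tktl2 (6.02, SE 1.44), Fam149b and Baz2b, higher in KO, and Hsdl2 (-5.36, SE 0.80), Pea15a (-7.56, SE 1.53), Asap2, Ikbip and Samd9l, lower in KO. Ly6a, which encodes the HSC surface antigen Sca-1 and is induced by interferon, stood at -4.28 (SE 1.33), Idh2 at -7.65 (SE 2.04), and Cdc45, a replication factor, at 2.39 (SE 0.73). By limma, 0 genes passed (lowest adjusted p = 0.856), and 1062 had an unadjusted p under 0.05. Across genes, which are not independent replicates, the KO against WT changes in primary and in secondary recipients correlated at r = 0.0699 (rho = 0.0626) and, without the dim arrays, at -0.00233. Of 54 genes at an unadjusted p under 0.05 in both (48.4 expected if independent), 31 had the same sign. Both changes use one spread estimate per gene, so the expected count is only a guide.

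The interaction asks whether the KO against WT change differs between the kinds of recipient. Mamdc2 (7.68, SE 1.36), Arhgef39 (10.06, SE 1.78), Bcdin3d, Rhox2a and Slc25a16 (8.97, SE 1.87) had the lowest p toward a higher change in secondary recipients, and Nars2 (-12.31, SE 2.42), Letm2, Ankrd49, Map1lc3b (-9.46, SE 2.04) and Wdr1 toward a lower one. The size for Slc25a16 rests on values near the floor, with scaled log2 levels of -8.58 and -8.11 in WT secondary cells. The sizes for Nars2 and Letm2 rest on such values too. In WT primary cells their levels were -7.41 and -4.32 (Nars2) and -7.49 and -4.35 (Letm2). On replicate 2 of KO secondary they were -7.97 and -8.08. Rad21 stood at -5.47 (SE 1.43). In limma 0 genes passed (lowest adjusted p = 1, with 857 at an unadjusted p under 0.05). None of the 24 lists did, the lowest camera adjusted p being 0.56 for DNA repair.

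**Figure D2:**
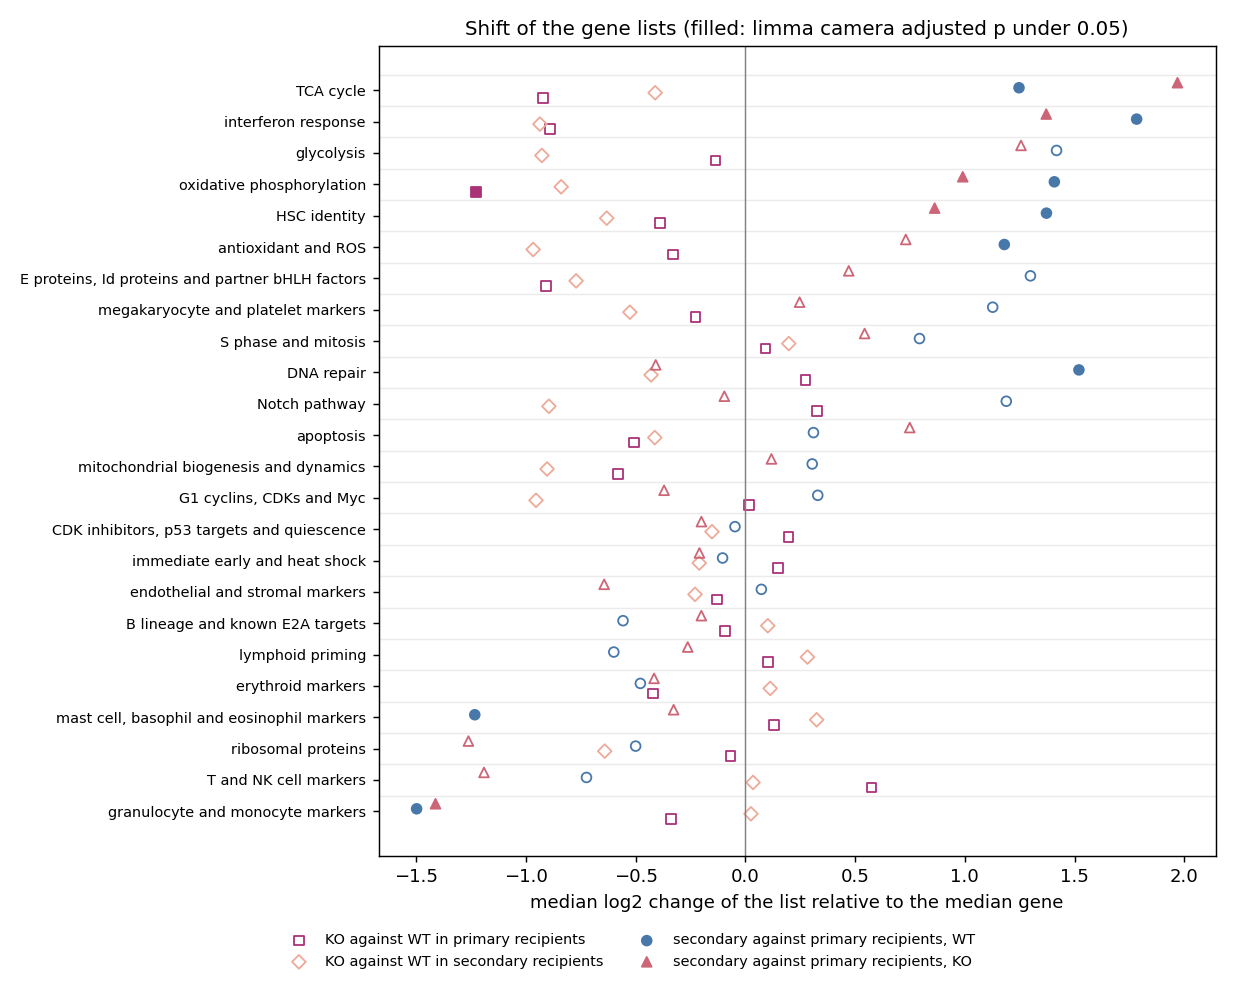
Median log2 change of each of the 24 gene lists relative to the median gene (horizontal axis), for KO against WT in primary (squares) and secondary (diamonds) recipients and for secondary against primary recipients in WT (circles) and KO (triangles) cells; filled symbols passed limma's camera at its preset correlation. Granulocyte and monocyte markers lay at -1.50 and -1.41 in the comparisons of recipients, and oxidative phosphorylation at 1.41 and 0.99.

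Cells from secondary and from primary recipients were compared over both genotypes, a comparison added after the data were seen. S100a8, which encodes a calcium-binding protein of neutrophils (chromosome 3, 90755783 to 90755842), had a signal of 10769 and 70779 (WT) and 11107 and 62443 (KO) in primary recipients, and of 2, 3, 81 and 2 in secondary recipients. Its log2 change was -14.23 (SE 1.88, limma adjusted p = 0.0616), a size that rests on values near the floor, since it was well above background on only 1 of the secondary arrays. Retnlg, secreted by granulocytes, stood at -12.15 (SE 1.85, 0.0617), S100a9, the partner of S100a8, at -11.77 (SE 1.99, 0.074), and Camp, an antimicrobial granule protein, at -9.55 (SE 2.04, 0.103). Without the dim arrays, S100a8 stood at -11.33, S100a9 at -8.39 and Retnlg at -9.81 (limma adjusted p = 0.059, 0.073 and 0.12). In that fit the list members Lcn2 (-10.67) and Mmp8 (-6.21) passed, each with a limma adjusted p = 0.048. The size for Lcn2 rests on values near the floor, since its signal was 2, 3, 2 and 2 in secondary recipients. In primary recipients its signal was 2471 and 32379 (WT) and 3362 and 2 (KO). The KO array that read 2 is a dim array left out of that fit, so the pass of Lcn2 depends on leaving it out. Granulocyte and monocyte markers as a list lay lower in secondary recipients (median -1.10, mean -3.34, 19 of 25 below the median gene, camera adjusted p = 0.0033; adjusted p = 0.28 with an estimated correlation), and 7 members passed when adjusted over the list alone.

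HSC identity genes lay higher in cells from secondary recipients (median log2 change 1.16, 26 of 32 above the median gene, adjusted p = 0.00089; adjusted p = 0.11 with an estimated correlation), with 3 members higher when adjusted over the list alone. The list's median level on replicate 2 of WT primary (3.183) nevertheless lay above that on 3 of the 4 secondary arrays (2.291, 2.379 and 2.72), and exact permutation over the arrays gave p = 0.114. Hlf, a transcription factor of HSC (chromosome 11, 90154754 to 90154813), stood at 5.66 (SE 0.70, limma adjusted p = 0.0617). The homeobox gene Meis1 stood at 5.92 (SE 0.84, 0.0751), and its other probe gave 0.56 in WT and 5.11 in KO cells. Oxidative phosphorylation was higher (median 1.40, 48 of 61 above, 9.6e-05, and adjusted p = 0.081 with an estimated correlation). The TCA cycle was too (1.02, 12 of 19 above, 0.0034, and adjusted p = 0.28 with an estimated correlation), with Suclg2 at 6.55 (SE 1.07) and Suclg1 at 4.55 (SE 0.77). Atp5d of ATP synthase stood at 4.34 (SE 0.71). When adjusted over the list alone, 5 TCA cycle genes and 0 oxidative phosphorylation genes passed. Interferon response genes were higher (1.70, 24 of 31 above, 0.0014, and adjusted p = 0.094 with an estimated correlation). Among them were the GTPase Gbp2 (7.27, SE 0.76) and Ifit1 (at least 46.6-fold), and 2 members passed when adjusted over the list alone. Each of these calls at the preset correlation held without any single array. Leaving out a single array still keeps a dim array among the primary recipients, so this does not test the dim arrays.

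Antioxidant genes were called higher (median 1.35, 24 of 36 above, camera adjusted p = 0.028, and adjusted p = 0.28 with an estimated correlation). Keap1 stood at 4.23 (SE 0.72) and Cat (catalase) was at least 11.5-fold higher, and 2 members passed when adjusted over the list alone. That call was lost without WT primary replicate 1 (0.091), WT secondary replicate 2 (0.053) or KO secondary replicate 1 (0.052). T and NK cell markers were called lower (-1.02, 16 of 19 below, 0.046, and adjusted p = 0.33 with an estimated correlation), with 0 members adjusted over the list alone. This call was lost without WT primary replicate 1 (0.072), KO primary replicate 2 (0.077), WT secondary replicate 2 (0.053) or KO secondary replicate 1 (0.14). Other lists did not pass and follow with median and adjusted p. They were glycolysis (0.78, 0.064), S phase and mitosis (0.30, 0.067), mast cell and basophil markers (-0.58, 0.067), B lineage genes (-0.60, 0.14), E and Id proteins (0.83, 0.14) and DNA repair (0.65, 0.14). Mki67, a marker of cycling cells, stood at 5.20 (SE 0.87). Nearer to chance were megakaryocyte markers (0.56, 0.32), mitochondrial biogenesis (0.35, 0.33), apoptosis (0.58, 0.33) and G1 cyclins (-0.07, 0.33). The rest were erythroid markers (-0.45, 0.42), CDK inhibitors (-0.21, 0.51), endothelial and stromal markers (-0.23, 0.51), ribosomal proteins (-0.80, 0.59), the Notch pathway (0.43, 0.60), lymphoid priming (-0.82, 0.70) and immediate early genes (0.13, 0.93).

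With limma, 0 genes passed in this comparison (lowest adjusted p = 0.0616). An unadjusted p under 0.05 was reached by 4477, 1252 higher and 3225 lower in secondary recipients, which is 28.0% higher. These directions are those before centring, and include a shift of the median gene by -0.76. The lowest p among genes higher in secondary recipients belonged to Mcee of propionate metabolism (6.83, SE 0.63), Ssty1, Gbp2, Serbp1 (7.89, SE 0.84), Mybbp1a, Pfdn1 (at least 219-fold), Cap1 (at least 78.8-fold), Gmfg, Pdcd5 and Map4. Genes lower there included, by p, S100a8, Retnlg, S100a9, Hormad1, Sdr9c7, Zc3h3, Cdh24, Tekt5 and Camp. The counts depended on the scaling, and the other settings gave 0 to 370 genes. The highest, 370 (367 higher, 3 lower), came with the 75th percentile taken over probes well above background on all arrays, where 85.4% of the genes at an unadjusted p under 0.05 were higher. With that scaling, chosen after the data were seen, the 3 lower genes were S100a8, Retnlg and S100a9 (limma adjusted p = 0.015, 0.018 and 0.024), and Gbp2 (0.011), Hlf and Meis1 (both 0.016) were among the higher ones. Without the dim arrays Gbp2, Hlf and Meis1 did not pass (limma adjusted p = 0.054, 0.096 and 0.12). Of the 370 genes, 40 also passed without the dim arrays. Exact two-sided permutation of the list levels over the arrays gave p = 0.0286, the smallest it can give with 4 arrays against 4, for granulocyte markers (-2.94), oxidative phosphorylation (1.38), the TCA cycle (1.58) and the interferon response (1.21), each with an adjusted p = 0.171. The other called lists did not reach that minimum in the exact permutation, with p = 0.114 for HSC identity (1.30), 0.0857 for antioxidant genes (1.49) and 0.0571 for T and NK cell markers (-1.57), each with an adjusted p = 0.229.

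**Figure D3:**
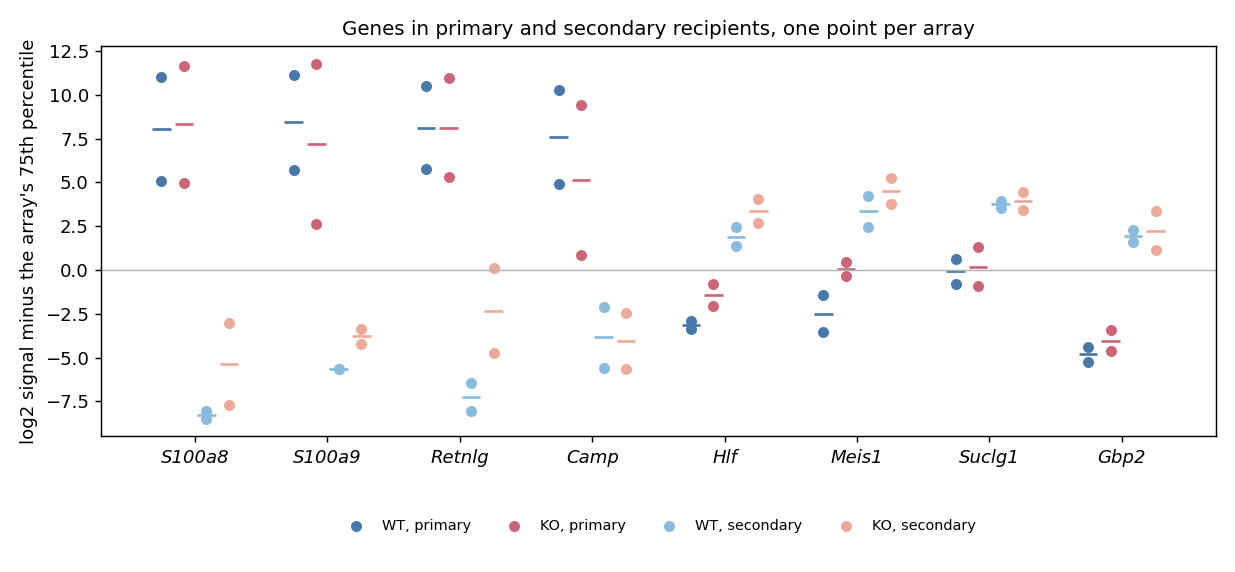
Log2 signal minus the array's 75th percentile for 8 genes, with a point per array and a line at the mean of each group of 2 arrays. S100a8, S100a9, Retnlg and Camp were higher on each array from primary recipients than on each from secondary recipients, and Hlf, Meis1, Suclg1 and Gbp2 lower.

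Within WT cells, whose arrays share a slide, secondary against primary recipients gave S100a8 at least 9540-fold, Retnlg at least 10100-fold and Lcn2, an iron-binding protein of neutrophil granules, at least 3090-fold lower in secondary recipients. These sizes rest in part on the scaling of dim replicate 2 of WT primary. The scaled log2 levels there were 10.99, 10.48 and 9.86 in this order, against 5.08, 5.76 and 2.96 on replicate 1. Higher in secondary recipients were Serbp1 (9.37, SE 1.11), the thrombin receptor F2r (at least 186-fold), Elp2, Mcee and Sub1, and Aoc2 and Ugt2b38 were lower. Granulocyte markers were called lower (median -1.50, 19 of 25 below, 6 adjusted over the list alone, camera adjusted p = 0.019, and adjusted p = 0.40 with an estimated correlation). So were mast cell markers (-1.23, 10 of 12 below, 0.031, and adjusted p = 0.31 with an estimated correlation). HSC identity was called higher (1.37, 24 of 32 above, 3 adjusted over the list alone, 0.0052, and adjusted p = 0.26 with an estimated correlation). Oxidative phosphorylation was called higher (1.41, 44 of 61 above, 0.007, and adjusted p = 0.25 with an estimated correlation). The interferon response was too (1.78, 25 of 31 above, 1 adjusted over the list alone, 0.0094, and adjusted p = 0.25 with an estimated correlation). The TCA cycle (1.25, 0.026, and adjusted p = 0.40 with an estimated correlation) and DNA repair (1.52, 0.026, and adjusted p = 0.42 with an estimated correlation) were also called higher. The last were antioxidant genes (1.18, 0.031, and adjusted p = 0.40 with an estimated correlation). The limma test left 0 genes (lowest adjusted p = 0.339, 2799 at an unadjusted p under 0.05). Without WT primary replicate 1 every call but that of oxidative phosphorylation was lost (HSC identity 0.36, interferon 0.13, granulocyte 0.066, mast cell 0.24, TCA cycle 0.54, DNA repair 0.23, antioxidant 0.43). WT secondary replicate 1 (TCA cycle 0.058, mast cell 0.076) and replicate 2 (DNA repair 0.16, antioxidant 0.11, mast cell 0.054) also decided calls.

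Within KO cells, whose groups lay on different slides, S100a8 stood at -13.15 (SE 2.76), with 1 of the 2 secondary arrays well above background, and S100a9 at -10.45 (SE 2.90), and Pebp4, Guca2a, Stk32c and Theg had the lowest p among the other genes lower in secondary recipients. Sae1 (7.32, SE 1.05), Ubap2l (6.58, SE 0.95), Mcee, Gmfg and the chaperone Hspa5 (at least 156-fold) led those higher. Oxidative phosphorylation was called higher (0.99, 46 of 61 above, camera adjusted p = 0.00036, and adjusted p = 0.13 with an estimated correlation). The TCA cycle (1.97, 0.015, and adjusted p = 0.56 with an estimated correlation) and the interferon response (1.37, 0.015, and adjusted p = 0.32 with an estimated correlation) were too. So was HSC identity (0.86, 0.015, and adjusted p = 0.49 with an estimated correlation), while granulocyte markers were lower (-1.41, 0.011, and adjusted p = 0.56 with an estimated correlation). All 5 calls, in this order, were lost without KO secondary replicate 1 (0.063, 0.31, 0.31, 0.23 and 0.063). Without KO primary replicate 2, all but that of the TCA cycle were lost (0.13, 0.15, 0.27 and 0.13), and the TCA cycle call was lost without KO primary replicate 1 (0.16). In limma 0 genes passed (lowest adjusted p = 0.696, 1381 at an unadjusted p under 0.05). The changes between recipients in WT and KO cells, which share no array, correlated across genes at r = 0.289 (rho = 0.268), and at 0.289 without the dim arrays. Of 470 genes at an unadjusted p under 0.05 in both (168 expected if independent), 434 had the same sign. Both changes use one spread estimate per gene from one fit, so the expected count may be too low. The p-values refer to changes before centring, and the median gene shifted by -1.03 in WT and -0.53 in KO cells. Each primary group also holds a dim array, so this is not independent replication.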

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

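Scaling by the 75th percentile of probes detected on all arrays, leaving out both dim arrays, array weights, and secondary against primary recipients over both genotypes were chosen only after results were seen. KO against WT gave 0 genes under every setting, apart from primary recipients without WT primary replicate 1 (range over single arrays left out 0 to 548). Secondary against primary over both genotypes gave 0 genes in the main setting and 1 with normexp, 205 with quantile normalization, 308 with the median of commonly detected genes, 89 with every probe by itself, 15 with the mean over probes, 38 with the trended robust variance, 42 with slide as a random block (correlation -0.0947), 370 with the common 75th percentile, 78 without the dim arrays and 107 with array weights. It gave 0 with the series matrix, without a filter, with the stricter filter, with a minimum fold, with the replicate block and without each array. Replicate numbers did not pair the arrays (r of deviations -0.0265 to 0.15), and the replicate block left every count of genes at 0. Lists past camera went from 1 to 0 in KO against WT in primary recipients with the estimated correlation, normexp, quantile normalization or no dim arrays (1 to 2 without single arrays). In secondary recipients they went from 0 to 5 with normexp, 4 without a filter, 1 with the replicate block, 5 without the dim arrays and 2 with array weights (0 to 3), and in the interaction from 0 to 2 without the dim arrays (0 to 1). Over both recipients they went from 4 to 0 with the estimated correlation, 2 with quantile normalization and 2 without the dim arrays (1 to 8). Between recipients they went from 8 to 0 with the estimated correlation in WT (2 to 12), from 5 to 0 with it and 9 with normexp in KO (0 to 7), and from 7 to 0 with it and 12 with normexp or quantile normalization over both genotypes (5 to 9). The direction that camera gives ribosomal proteins in KO against WT over both recipients reversed only without WT primary replicate 2 (adjusted p = 0.77, range over single arrays left out 3.1e-08 to 0.77). Their median change also turned positive without KO primary replicate 1. The cause was not tested in any of these. Of 10252 values of named genes, 98.9% kept their sign, while 878 changed sign or shifted by more than their SE. Many of these genes were picked for a low p, and the settings share arrays, so a kept sign says little. Of 450 values of called lists, 84 lost the call. A left-out array leaves a lone array assumed to vary like the others. Slide could be fitted as a random block only in the comparisons over all 8 arrays. The low signal on the dim arrays limits what primary recipients can show.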

Other observations

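Tests of the dim arrays, slides and abundance, the correlation between probes of one gene in its present form, and the counts of splits for genes past the test were chosen only after the results they bear on were seen, as was asking the list tests to hold with an estimated correlation or in single members, a rule changed more than once with the values known. Also afterwards, a comparison of replicate differences with spot noise, and of ribosomal genes with all genes, was dropped as a test of an explanation because a spread between single samples set against technical noise decides nothing. Its values remain as measurements: the median absolute deviation between replicates was 1.43, 3, 0.165 and 0.489 over 60 ribosomal genes and 2.27, 2.36, 1.22 and 1.61 over all genes (WT primary, KO primary, WT secondary, KO secondary).

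Xist, the RNA that silences an X chromosome in female cells, was measured by 4 probes. All 4 lay between 0.88 and 3.63 on the log2 scale above the 75th percentile on the 4 arrays from secondary recipients. On arrays from primary recipients they ranged from -7.36 to 8.72, the brightest probe reading 147 and 14696 in WT and 820 and 2 in KO cells. Y-linked Ddx3y reached 74 and 220 in WT secondary and 5 and 2 in KO secondary cells, and Eif2s3y 14 and 297, and 26 and 4. Uty stood at 3.58 (SE 1.12, limma adjusted p = 0.81) for KO against WT in secondary recipients. That size rests on values near the floor: Uty read 2 and 3 in WT and 46 and 19 in KO secondary cells. It was well above background on 0 of these WT arrays.

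Granulocyte markers were higher in cells from primary recipients. Low signal on the dim arrays is argued against as the whole cause, since without them the list's median was -1.03 (limma camera adjusted p = 0.0042, though 0.27 with an estimated correlation, against 0.28 with all arrays) and 8 members were lower by limma adjusted over the list alone. A slide effect is argued against in WT cells, whose arrays share slide 1 and gave a median of -1.50 (limma camera adjusted p = 0.02, though 0.43 with an estimated correlation) with 6 such members, while in KO cells (-1.41) slide and recipient cannot be told apart. RNA of mature granulocytes in the primary samples, which a sort for HSC would be meant to exclude, may contribute: 30 late neutrophil genes outside the list were written down first, and of 26 tested 17 lay below the median gene, with a median of -0.55. The criterion set beforehand, a median below the 2.5th percentile of matched lists (-0.646), was not met (percentile 5.06), and a bootstrap interval added only after that miss (-1.34 to 0.172) spans the criterion, so this stays open, with 4 of the genes higher on every primary array, 0 lower, and 12.9% of all genes doing so where chance gives 1.43%.

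Oxidative phosphorylation genes were called lower in KO, in primary and over both recipients, by camera at the preset correlation only. The call was lost with an estimated correlation, and exact permutation of the list levels over all 8 arrays gave p = 0.457. Mean level of the members over the 8 arrays as the sole cause is argued against by a percentile of 0 among random lists matched on it. Levels on single arrays, such as the dim ones, were not matched. The random lists hold unrelated genes, whose medians spread less than those of genes that move together. The percentile therefore does not exclude chance. The dim arrays as the cause stay open over both recipients, with a median of -0.68 without them (limma camera adjusted p = 0.0019, 0.52 with an estimated correlation, and 0 members past limma over the list alone), and within primary recipients, with a median of -0.61 (0.36 and 0.81). Slide and genotype cannot be told apart, since 0 slides hold both genotypes. A loss through missing E47 remains untested beside these.

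Replicate arrays differed probe by probe, and no biological explanation was tested. A difference in the RNA level of whole genes stays open: over all pairs above background, probes of one gene deviated together at r = 0.148 at most, but their levels also correlated at only 0.202 to 0.321. Unequal amplification of cDNA fragments is a candidate explanation, thought of after the first of these values was seen but with its prediction written before its own test: probes at most 100 bases apart deviated together at 0.667 or more in each group, and probes over 1 kb apart at 0.0154 to 0.076. Levels of these distant probes correlated at 0.134 to 0.26, so the fall with distance does not single out this explanation. Low signal stays open, with r = 0.498 at most (0.222 at least) among the brightest pairs.

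The 8 arrays were split into 4 and 4 in 34 ways, the real split included, and counts of splits below include it. For KO against WT over both recipients, the real split gave 4 lists, reached by 2 splits, with 6 in the highest other, so chance is not excluded. For secondary against primary recipients it gave 7 lists, reached by 2 splits, with 8 in the highest other, where chance is not excluded. Both real splits gave 0 genes past limma's test (1062 and 4477 at an unadjusted p under 0.05), which all 34 splits reach by necessity, so this count bears on nothing. The highest other was 24 genes for KO against WT, in the split that sets WT primary replicate 1, both KO primary arrays and KO secondary replicate 2 apart, and 0 for the recipients. The recipient split gave 4477 genes at an unadjusted p under 0.05, reached by 1 split with 2134 in the highest other, and 370 genes with the common 75th percentile, reached by 1 split with 28 in the highest other. No other split reached either count. The comparison was, however, added after the data were seen. The labels also leave open whether the 2 arrays of a group are separate samples. Both of these highest other splits set the 2 dim arrays on the same side, as the recipient split does. Chance is therefore not excluded by these counts. Scaling by the common percentile gave the highest count of the settings run (0 to 370) and was chosen after the data were seen. The split by the other factor could not be fitted.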
